A study of Mus musculus with 8 samples.

How the data were processed

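RNA from the posterior trunk of mouse embryos at embryonic day 9.5 was measured in 8 libraries: 2 wild type (WT), 3 heterozygous for a Prtg knockout allele (Het) and 3 homozygous (KO). Per the labels' protocols, poly(A) RNA was selected, fragmented and primed with random primers, and libraries were made with a kit that, as named there, does not mark strand. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 and the builds GRCm38 and mm10, without giving their roles or order. The annotation release and the strand setting of the counting are not given in the sources used here.

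The authors deposited 1 table with a whole-number read count per gene and library, not normalized, beside the exonic length, position and symbol of each gene. The deposited table holds 55573 genes. It also holds 8 columns of FPKM per library, which were not used; FPKM values here were computed from the counts, the column totals and the exonic lengths. Coordinates are those of the deposited table. The column names give the genotype and a pair of numbers that match no sample number in the labels, so each column was assigned to its genotype only. A library is named by its genotype and those numbers, as in KO 1-3, and the first number is called the column set. Its meaning is not given in the sources used here.

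Total counts per library lay between 16874860 and 17511964. PCR copies cannot be told from separate molecules in such counts, so their sampling error is a lower bound on the technical error. Each library was counted as 1 replicate, as labelled. No pair of libraries of 1 genotype agreed within sampling noise (variance 2.21 to 9.50 times that of counting), so none were merged, which does not show that they came from separate embryos.

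The design fixed before the data were examined was a test on log2(FPKM + 1), to be replaced by a count test if raw counts were given. Raw counts were given, so edgeR 4.0.16 (R 4.3.3) was used: TMM scaling, the default expression filter, which kept 16262 genes, and the quasi-likelihood test with 1 mean per genotype in a single fit of all 8 libraries. The contrasts were KO minus WT, KO minus Het, Het minus WT, and KO minus the mean of WT and Het. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Standard errors were derived from the fold change and the quasi-likelihood F statistic. Levels are CPM, counts scaled to the same total in each library after TMM scaling, given as mean ± SD.

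Of 42 gene lists fixed before the data were examined, 41 had at least 3 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of 1 contrast, and again with an estimated correlation and with fry. The level of a list in a library is the median over its members of log2(CPM + 1) minus the mean of the 5 WT and Het libraries. A Hox index was computed per library as the mean log2(FPKM + 1) of Hox paralogue groups 10 to 13 minus that of groups 5 to 9, over members with an FPKM of at least 1 in at least 2 libraries. It was compared with exact two-sided permutation tests in SciPy 1.17.1.

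The rule for named genes was also fixed before the data were examined. It takes Prtg, up to 10 called genes per direction and pairwise comparison with the largest change, no overlap between the groups and at least 5 FPKM in the higher group, the called Hox genes and the 4 with the smallest p per Hox list, called members of the other lists or the 1 to 2 with the smallest p, and a fixed set of regulators of the body axis and of GDF11 signalling. Where no gene was called, the 3 with the smallest p per direction are given.

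The count test and the list tests were tested on simulated counts with 200 genes changed and a planted list of other genes lowered 2-fold. Camera called the planted list in each comparison, also with an estimated correlation (highest adjusted p = 1.59e-04). Genes were simulated independently, so this does not show how the list tests fare when genes of a list vary together. In the simulation of KO minus WT on 15969 genes, 38.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 90.9% of those changed 4-fold were recovered, and 9.82% of the calls were false. For KO minus Het the shares were 53.7%, 73.1% and 90.9%, with 10.6% false calls. For KO minus the mean of WT and Het they were 55.2%, 74.6% and 92.4%, with 7.91% false calls. For Het minus WT, on 15986 genes, they were 34.3%, 71.6% and 89.4%, with 9.49% false calls. The share of false calls thus lay above the nominal 5% in each simulated comparison. The comparisons with KO used the same simulated counts, so their shares are not independent.

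Alternatives were DESeq2 1.42.0, edgeR with DESeq2 size factors, limma on log2 FPKM with other pseudocounts, scalings, weights and moderation, other filters on low counts, fits of only the compared libraries, the level of Y-linked genes as a covariate, a linear trend over knockout alleles, and leaving out each library in turn. The column set as a block, limma on log2(FPKM + 1) and the Y-linked covariate for the list tests were added after seeing the data. Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9 were used for the index and the plots.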

Results

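Poly(A) RNA was sequenced from the posterior trunk of C57BL/6 mouse embryos at embryonic day 9.5, the part behind a division between somites 12 and 13. The embryos came from matings of mice heterozygous for a knockout allele of Prtg, which encodes protogenin, a transmembrane receptor of the immunoglobulin superfamily related to Dcc and neogenin. There were 2 wild-type (WT), 3 heterozygous (Het) and 3 homozygous knockout (KO) libraries, and n is 2, 3 and 3 throughout. Total gene counts ran from 16874860 in Het 1-1 to 17511964 in KO 2-3, and 16262 of 55573 genes were tested. The labels do not name litters, so p-values measure only the spread between these samples. Xist, the transcript of the inactive X chromosome, was at 803 to 1101 CPM in WT 1-2, Het 1-1, Het 2-4 and KO 1-3 and at 1.52 to 3.57 CPM in the other libraries. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and fold changes are log2 values ± SE.

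Prtg (chromosome 9, 72806874 to 72917291, GRCm38) was measured first, in every library. Its level was 317 and 386 CPM in the WT libraries, 250, 240 and 282 CPM in the Het libraries, and 268, 254 and 237 CPM in the KO libraries. The KO minus WT value of Prtg was -0.47 ± 0.10 (edgeR adjusted p = 0.148), that of Het minus WT was -0.45 ± 0.10, and that of KO minus Het was -0.03 ± 0.09 (edgeR adjusted p = 0.932). The KO and Het values overlapped. DESeq2 called the Prtg level in KO against WT (-0.48, adjusted p = 8.51e-04), as did edgeR with no filter on low counts (-0.48, adjusted p = 4.47e-04). The deleted part of the gene is not given in the sources used here, so whole-gene counts are a weak check of the genotype labels. Without Het 2-5 or KO 2-3 the KO minus Het value changed sign (0.044 and 0.019).

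The comparison of KO with WT asks what the loss of both Prtg alleles changes. In KO embryos, 6 genes fell and 0 rose. With no filter on low counts the genes that differ between KO and WT numbered 100 higher and 105 lower in edgeR. Fst, which encodes follistatin, a secreted binding protein of activins and GDF11, fell from 21.3 ± 1.75 to 5.73 ± 0.671 CPM (-1.89 ± 0.13, edgeR adjusted p = 3.17e-04). Pmepa1, a target and inhibitor of TGF-beta signalling, fell from 4.44 ± 0.408 to 0.853 ± 0.136 CPM (-2.37 ± 0.24, edgeR adjusted p = 0.00563). Spock2, which encodes an extracellular proteoglycan, fell from 39.7 ± 5.21 to 17.9 ± 1.06 CPM (-1.15 ± 0.11, edgeR adjusted p = 0.00312). The Hox genes Hoxa11 (-2.05 ± 0.22, edgeR adjusted p = 0.00587) and Hoxc11 (-2.76 ± 0.33, edgeR adjusted p = 0.0125) fell, from 21.1 ± 6.92 to 5.10 ± 1.02 CPM and from 11.5 ± 3.95 to 1.68 ± 0.686 CPM. The other called gene was Spaca6 (-1.72 ± 0.19, edgeR adjusted p = 0.00587), named after its values were seen. Fst lies on chromosome 13 (114452290 to 114458951), Pmepa1 on 2 (173224458 to 173276533), Spock2 on 10 (60106219 to 60135198), Hoxa11 on 6 (52242106 to 52245810), Hoxc11 on 15 (102954427 to 102957708) and Spaca6 on 17 (17827158 to 17843009). In all 6 genes the KO and WT libraries did not overlap. Chance gives this for 20% of unselected genes with 3 against 2, but these were selected by a test on the same libraries, so it adds no support. Among genes short of the threshold were Nr6a1, a nuclear receptor gene active in the trunk stage, at 0.67 ± 0.11 (edgeR adjusted p = 0.0626), Btg2 at -0.91 ± 0.14 (edgeR adjusted p = 0.0561) and Mns1 at -0.66 ± 0.10 (edgeR adjusted p = 0.0554). The edgeR count of 0 higher genes stands beside 1170 genes of either direction at an unadjusted p below 0.05, and DESeq2 called 25 higher and 66 lower genes and limma on log2(FPKM + 1) 1 higher and 2 lower. Fst was called in each of the 8 fits that left out 1 library. Without WT 1-2 it was the 1 gene called, and the adjusted p was 0.170 for Hoxc11 and 0.0779 for Hoxa11, Pmepa1, Spock2 and Spaca6; without KO 2-2, Hoxa11 (0.0504) and Hoxc11 (0.0528) were not called, without WT 2-1 Spaca6 (0.0656) was not, and without KO 1-3, 28 genes were called.

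**Figure D1:**
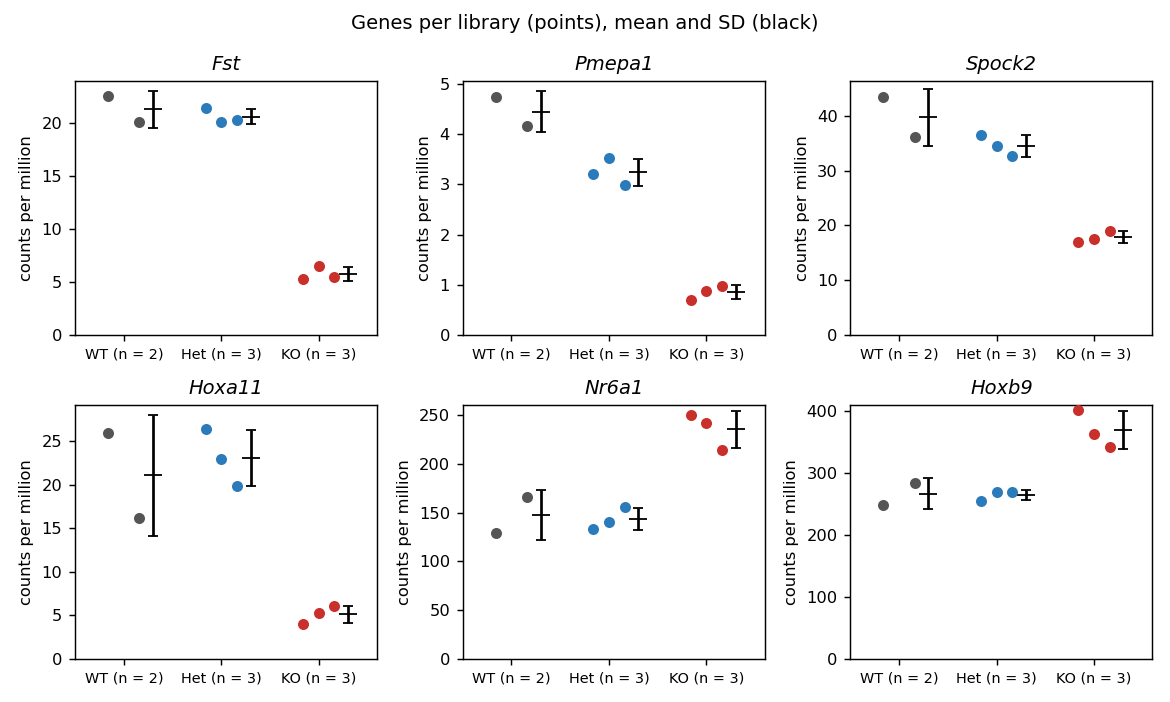
Levels of 6 genes in CPM on the vertical axis, by genotype on the horizontal axis. Points are libraries and black marks are the mean and SD. Fst lies between 5.24 and 6.50 CPM in the KO libraries and between 20.1 and 22.5 CPM in the others.

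The study's title names a switch of the Hox code from trunk to tail, so Hox genes were compared by paralogue group. Of the 12 genes of groups 10 to 13, which pattern the lumbar to tail region, 10 were tested, and all 10 had values below 0 in KO against WT, from -3.57 to -0.85 with a median of -1.46. Of these, 2 were called lower over all genes and 9 when adjusted over the list alone. Hoxd11 (-2.54 ± 0.39, edgeR adjusted p = 0.0554), Hoxd13 (-1.40 ± 0.28, edgeR adjusted p = 0.142) and Hoxa10 (-0.85 ± 0.15, edgeR adjusted p = 0.0871) were short of the threshold. Neither called gene was called without WT 1-2 or without KO 2-2, where 0 tail Hox genes were called by edgeR over all genes, while 6 were called without KO 1-3 and 3 without WT 2-1 and without KO 2-3. The list median stayed at -1.46 in edgeR with DESeq2 size factors and in DESeq2. It was -1.28 and -1.30 in limma on log2 FPKM scaled by the median of ratios or by quantiles, where the test and the pseudocount changed too. The list was called lower by camera (adjusted p = 1.15e-47), but not with its correlation estimated (adjusted p = 0.0530 with an estimated correlation) or with fry (adjusted p = 0.0541).

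Hox genes of more anterior groups lay on both sides of 0. In groups 5 to 9, 8 of 15 values lay above 0 and 7 below, with a median of 0.01 (camera adjusted p = 0.390), and 1 gene was called higher when adjusted over the list alone. Without WT 2-1 camera called the list higher (median 0.15, adjusted p = 0.0415, adjusted p = 0.430 with an estimated correlation). Their values ran from Hoxc9 at -0.25 ± 0.08 to Hoxb9 at 0.47 ± 0.08 (edgeR adjusted p = 0.0961), with Hoxb8 at 0.28 ± 0.10 and Hoxd9 at -0.23 ± 0.09. In groups 1 to 4, 8 of 12 values lay above 0 and 4 below, with a median of 0.13 (camera adjusted p = 0.189), and 0 genes were called over all genes or over the list alone by edgeR. Hoxc4 was at 0.47 ± 0.18, Hoxd1 at 0.36 ± 0.14, Hoxb3 at 0.18 ± 0.09 and Hoxb1 at -0.16 ± 0.07. Leaving out 1 library gave 0.23 to 0.62 for Hoxc4, 0.22 to 0.48 for Hoxd1, 0.12 to 0.23 for Hoxb3 and -0.20 to -0.12 for Hoxb1.

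The tail minus trunk Hox index was -3.04, -2.49 and -2.34 in the KO libraries, -0.98 and -1.59 in WT and -0.97, -1.22 and -1.45 in Het, from 9 tail and 15 trunk genes. The mean was -2.62 ± 0.37 (SD, n = 3) in KO and -1.24 ± 0.28 (SD, n = 5) in the other libraries, a difference of -1.38 (exact two-sided permutation p = 0.0357, the smallest that 56 splits allow, and 0.143 after adjustment over 4 comparisons). The pairwise differences were -1.34 for KO against WT (exact p = 0.2), -1.41 for KO against Het (exact p = 0.1) and 0.07 for Het against WT (exact p = 0.8), where the first 2 are the smallest p these group sizes allow. Within the column sets the KO libraries lay -2.06 and -0.99 from the others, where the first value rests on KO 1-3 against WT 1-2 and Het 1-1. These libraries of the first set were all high in Xist, so column set and sex overlap in part. Permuting genotypes within the sets gave an exact p of 0.0667, the smallest of 30 splits. Leaving out 1 library gave -1.17 to -1.52, with exact p of 0.0571 or 0.0952, again the smallest allowed. The Het minus WT difference was -0.23 without WT 2-1 and -0.051 without Het 1-1.

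**Figure D2:**
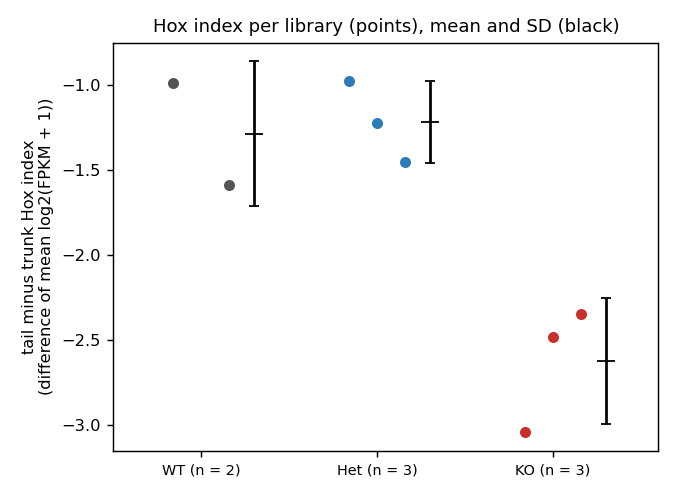
Tail minus trunk Hox index on the vertical axis, a difference of mean log2(FPKM + 1), by genotype on the horizontal axis. Points are libraries and black marks are the mean and SD. The KO libraries lie between -3.04 and -2.34 and the others between -1.59 and -0.97.

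The comparison of KO with Het, with 3 libraries each, called 31 genes, 10 higher and 21 lower. Fst fell by 1.84 on the log2 scale (SE 0.12, edgeR adjusted p = 1.93e-04) and Pmepa1 by 1.91 (SE 0.23, edgeR adjusted p = 0.0134). Of the tail Hox genes 6 were called lower and 9 when adjusted over the list alone: Hoxa11 (-2.18 ± 0.21), Hoxc11 (-2.71 ± 0.31), Hoxd11 (-2.53 ± 0.37), Hoxd10 (-1.44 ± 0.23), Hoxd13 (-1.55 ± 0.26) and Hoxa10 (-0.90 ± 0.14). The list median was -1.49 (camera adjusted p = 7.74e-46, adjusted p = 0.0565 with an estimated correlation, fry adjusted p = 0.0525), and 1 to 6 of its genes were called lower in the fits that left out 1 library. Hoxa11os (-1.86 ± 0.31), which overlaps Hoxa11, also fell, but reads of the pair cannot be told apart without strand where the genes overlap. Other genes that fell were Spock2 (-0.95 ± 0.10), Tmem119 (-0.81 ± 0.10), Mfap4 (-1.08 ± 0.17), which encodes a microfibril-associated protein, and the immediate early gene Btg2 (-0.81 ± 0.13, edgeR adjusted p = 0.0445). Btg2 was called in 0 of the 8 edgeR fits that left out 1 library (highest adjusted p = 0.234), Mfap4 and Hoxd10 in 1 (highest adjusted p = 0.225), Hoxa10 and Hoxd13 in 2, Hoxa11os in 3, Pmepa1, Tmem119 and Hoxd11 in 4, Hoxc11 in 5 and Spock2 in 6. Fst and Hoxa11 were called in each fit that left out 1 library, and they were the 2 genes called without Het 1-1 and without Het 2-4. The count was 18 without WT 1-2, 15 without WT 2-1, 5 without Het 2-5, 6 without KO 2-2 and 49 without KO 1-3.

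Among the 10 genes that rose in KO against Het were Nr6a1, Hoxb9, Msx1, Irx3, Cer1, Dact2 and Rnf213. Nr6a1 rose from 143 ± 11.5 to 236 ± 18.8 CPM (0.72 ± 0.10, edgeR adjusted p = 0.0261), and the trunk Hox gene Hoxb9 from 264 ± 8.30 to 369 ± 30.2 CPM (0.48 ± 0.07, edgeR adjusted p = 0.0407). The homeobox genes Msx1 (0.65 ± 0.09, edgeR adjusted p = 0.0261) and Irx3 (0.39 ± 0.06, edgeR adjusted p = 0.0330) rose, as did Cer1, which encodes a secreted antagonist of Nodal, BMP and WNT ligands (1.19 ± 0.18, edgeR adjusted p = 0.0383), Dact2 (0.77 ± 0.09, edgeR adjusted p = 0.00930) and Rnf213 (0.72 ± 0.11, edgeR adjusted p = 0.0349). Vegfb was called higher (0.53 ± 0.09, edgeR adjusted p = 0.0449), with 47.8 ± 4.54 CPM in KO, 33.2 ± 2.24 in Het and 46.6 ± 0.793 in WT. All 31 called genes had no overlap between the groups. Chance gives this for 10% of unselected genes with 3 against 3, but these were selected by a test on the same libraries, so it adds no support. None of the genes named as higher was called without Het 1-1 or Het 2-4, and the highest adjusted p of Vegfb was 0.257. Cer1 and Vegfb were called in 1 of the 8 fits that left out 1 library, Irx3 and Rnf213 in 2, Hoxb9 in 3, Nr6a1 in 4, Msx1 in 5 and Dact2 in 6. The lists of trunk-stage regulators, with 1 of 10 genes called higher over all genes and over the list alone, and of neural tube progenitors, with 2 of 20 over all genes and 3 higher and 1 lower over the list alone, were not called (camera adjusted p = 0.156 and 0.0812). Camera called the neural tube list higher without KO 1-3 (adjusted p = 0.00735, adjusted p = 0.552 with an estimated correlation) and without Het 1-1 (adjusted p = 0.0131, adjusted p = 0.644 with an estimated correlation), and the trunk-stage list higher without Het 2-5 (adjusted p = 0.0435, adjusted p = 0.418 with an estimated correlation). In KO against WT the neural tube list was called higher without KO 1-3 (adjusted p = 0.00825, adjusted p = 0.543 with an estimated correlation) and without WT 1-2 (adjusted p = 0.00228, adjusted p = 0.327 with an estimated correlation). DESeq2 called 66 higher and 93 lower genes, and limma on log2(FPKM + 1) called 4. With no filter on low counts the genes that differ between KO and Het numbered 256 higher and 181 lower in edgeR.

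Against the mean of WT and Het, which both keep at least 1 intact allele, 12 genes rose and 42 fell in KO. With no filter on low counts the genes that differ between KO and the mean of WT and Het numbered 307 higher and 207 lower. The tail Hox genes called lower numbered 8, and 9 when adjusted over the list alone: Hoxa10 (-0.88 ± 0.13), Hoxa11 (-2.11 ± 0.20), Hoxc10 (-1.48 ± 0.26), Hoxc11 (-2.73 ± 0.30), Hoxd10 (-1.41 ± 0.21), Hoxd11 (-2.53 ± 0.35), Hoxd12 (-3.61 ± 0.64) and Hoxd13 (-1.48 ± 0.24). Leaving out 1 library gave 2 to 8 of them. The list median was -1.48 (camera adjusted p = 5.16e-48, adjusted p = 0.0508 with an estimated correlation), and fry called the list lower (adjusted p = 0.0438). Hoxd12 rested on 0, 2 and 6 reads in the KO libraries and 18 to 48 in the others. Fst (-1.87 ± 0.12, edgeR adjusted p = 8.43e-05) and Pmepa1 (-2.14 ± 0.22, edgeR adjusted p = 0.00324) fell, as did the hindlimb regulators Tbx4 (-0.93 ± 0.16, edgeR adjusted p = 0.0395) and Pitx1 (-0.47 ± 0.07, edgeR adjusted p = 0.0281), the kidney and mesothelium regulator Wt1 (-1.30 ± 0.22, edgeR adjusted p = 0.0426) and the SMAD corepressor gene Skil (-0.43 ± 0.07, edgeR adjusted p = 0.0426). Nr6a1 (0.69 ± 0.09), Hoxb9 (0.48 ± 0.07), Msx1 (0.55 ± 0.08), Irx3 (0.35 ± 0.05) and Cer1 (1.13 ± 0.16) rose. Mns1 (-0.55 ± 0.08, edgeR adjusted p = 0.0183), which lies near Prtg on chromosome 9, was the 1 called gene among 61 tested within 5 Mb of it. All 54 called genes had no overlap between the KO and the other libraries. Chance gives this for 3.57% of unselected genes with 3 against 5, but these were selected by a test on the same libraries, so it adds no support. This contrast shares its libraries with the pairwise ones and is not independent of them. Of the 54 genes 9 were called in each fit that left out 1 library, among them Fst, Pmepa1, Hoxa11, Hoxc11 and Spock2, and Nr6a1 was lost without Het 2-4 alone (adjusted p = 0.0621). Each of the other genes named here lost its call without WT 1-2 and without Het 2-4, among other libraries. Skil (highest adjusted p = 0.139) and Hoxd12 were called in 1 of the 8 fits, Tbx4 (0.147), Pitx1 (0.105), Wt1 (0.157) and Hoxc10 in 2, Irx3, Cer1, Mns1, Hoxa10 and Hoxd13 in 3, Hoxd11 in 4 and Hoxb9, Msx1 and Hoxd10 in 5. The count was 11 without WT 1-2, 21 without WT 2-1, 16 without Het 1-1, 9 without Het 2-4, 29 without Het 2-5 and 34 without KO 2-2. DESeq2 called 79 higher and 125 lower genes.

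**Figure D3:**
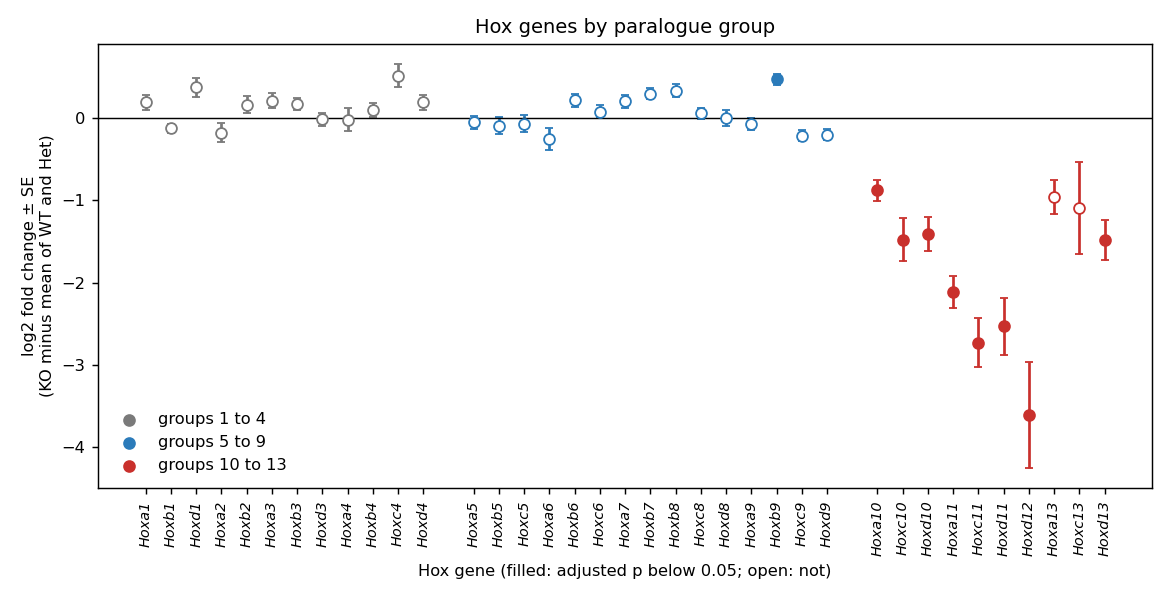
Log2 fold change of each tested Hox gene, KO minus the mean of WT and Het, with its SE, by paralogue group. Filled points passed an adjusted p of 0.05 and open points did not. All 10 genes of groups 10 to 13 lie below 0, between -3.61 and -0.88.

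The comparison of Het with WT asks what the loss of 1 allele changes, and edgeR called 0 genes. At an unadjusted p below 0.05 there were 292 genes, DESeq2 called 2, and limma on log2(FPKM + 1) called 0. The smallest adjusted p was that of Mat2a, which encodes a methionine adenosyltransferase, with 11.1 ± 4.24 CPM in WT, 37.3 ± 6.35 in Het and 35.5 ± 8.30 in KO (1.75 ± 0.25, edgeR adjusted p = 0.429). Ripply2 was at 0.94 ± 0.23, Nme3 at 1.89 ± 0.51, Vegfb at -0.49 ± 0.10 and Gnas at -0.26 ± 0.06. The tail Hox median was 0.01, with 5 of 10 values above 0. Camera called 6 lists lower, among them yolk sac endoderm at a median of -0.44 (adjusted p = 0.00269), with Ttr at -0.79 ± 0.42 and Fgb at -0.83 ± 0.44, and neuromesodermal progenitor and tailbud genes at -0.07 (adjusted p = 0.0362), with Sp5 at -0.43 ± 0.15 and 0 genes called over either list alone by edgeR. With an estimated correlation none of the 6 was called (adjusted p = 0.958 for both of these lists with an estimated correlation). Leaving out 1 library gave -1.23 to -0.45 for Ttr, -1.13 to -0.66 for Fgb and -0.59 to -0.25 for Sp5. The median of the progenitor list was 0.094 without WT 2-1 (adjusted p = 0.429), -0.18 without WT 1-2, -0.11 without Het 2-5 and 8.6e-04 without Het 1-1 (adjusted p = 0.516), and the list was not called without Het 2-4 (adjusted p = 0.115). Yolk sac endoderm was at -0.71 without WT 1-2 and was not called without WT 2-1 (-0.16, adjusted p = 0.0725) or Het 1-1 (adjusted p = 0.123). Without KO 1-3, Mat2a was called (edgeR adjusted p = 0.0395), without WT 1-2 camera called 12 lists, and without Het 1-1 or Het 2-4 it called 2.

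Of 41 gene lists camera called 14 in KO against WT, 5 higher and 9 lower, and 15 in KO against Het, 7 higher and 8 lower, and with an estimated correlation it called 0 in both. The title also names GDF11 and SMAD2, a ligand and a signal transducer of the activin branch of TGF-beta signalling. The mRNA of the main components of the pathway named here did not pass the test in KO against WT. Such counts do not measure the amount or the activity of the proteins, so they leave the state of this signalling open. Gdf11 was at 83.4 ± 0.449 CPM in WT, 85.2 ± 6.43 in Het and 90.7 ± 17.2 in KO (0.12 ± 0.13, edgeR adjusted p = 0.870), where KO 1-3, at 70.8 CPM, lay below and KO 2-2 and KO 2-3, at 100 and 101 CPM, above the range of 77.8 to 89.0 in the WT and Het libraries. Its KO minus WT value was 0.27 without KO 1-3 (edgeR adjusted p = 0.254), 0.046 without KO 2-2 and 0.035 without KO 2-3. Smad2 was at 86.3 ± 2.59, 85.3 ± 2.44 and 85.0 ± 3.86 CPM (-0.02 ± 0.06, edgeR adjusted p = 0.963). The receptor genes Acvr1b (-0.08 ± 0.10), Acvr2b (0.05 ± 0.07) and Tgfbr1 (-0.04 ± 0.07) were not called, with Acvr1b at -0.16 without KO 1-3 and -0.0091 without KO 2-2. Acvr2b ran from 0.029 to 0.080 when 1 library was left out. Of 23 tested ligands, receptors and SMADs, Fst alone was called, over all genes and over the list alone, and the list median was -0.04 (camera adjusted p = 0.0396, adjusted p = 0.229 with an estimated correlation). KO 1-3 lay at 0.10, KO 2-2 at -0.036 and KO 2-3 at -0.024, against -0.025 to 0.028 in the WT and Het libraries, and the call was lost without KO 2-2 (median -0.0075) or KO 2-3 (highest adjusted p = 0.137). Of 18 tested SMAD2/3 target genes Pmepa1 was called lower, 3 were lower when adjusted over the list alone, and the median was -0.20 (camera adjusted p = 5.51e-05, adjusted p = 0.137 with an estimated correlation), with Skil at -0.42 ± 0.09. The target list lay at 0.065 in KO 1-3, within the WT and Het range of -0.064 to 0.087, and at -0.23 in KO 2-2 and -0.16 in KO 2-3. In KO against Het the target list had a median of -0.12 (camera adjusted p = 0.00523, adjusted p = 0.389 with an estimated correlation), and was not called without Het 1-1 (-0.043, adjusted p = 0.0699), KO 2-2 (adjusted p = 0.0717) or KO 2-3 (-0.068, adjusted p = 0.0651), while without KO 1-3 the median was -0.19. Smad2 changed sign without WT 1-2 (0.0071) or KO 1-3 (0.0022) and Tgfbr1 without KO 1-3 (0.033).

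Regulators of the tail stage, hindlimb and cloaca had a median of -0.16 over 14 tested genes in KO against WT (camera adjusted p = 2.00e-05, adjusted p = 0.0887 with an estimated correlation), with 0 called by edgeR over all genes and 1 higher and 5 lower when adjusted over the list alone. Without Het 2-5 the median was -0.10. Tbx4 was at -0.91 ± 0.19, Pitx1 at -0.47 ± 0.09 and Isl1 at -0.63 ± 0.17. The list shares Hoxa13 (-0.98), Hoxc13 (-1.15) and Hoxd13 (-1.40) with the tail Hox list, so its call is not separate from that of the tail Hox genes. Of 27 tested neuromesodermal progenitor and tailbud genes Fst alone was called in KO against WT, over all genes and over the list alone (median 0.09, camera adjusted p = 0.742). Camera called this list lower without WT 1-2 (median 0.023, adjusted p = 0.0316, adjusted p = 0.439 with an estimated correlation) and higher without WT 2-1 (median 0.19, adjusted p = 0.00909, adjusted p = 0.407 with an estimated correlation). Of 10 trunk-stage regulators 0 were called by edgeR over all genes and Nr6a1 was higher when adjusted over the list alone (median 0.04, camera adjusted p = 0.425), a list that camera called higher without WT 2-1 (adjusted p = 0.0265, adjusted p = 0.430 with an estimated correlation). T was at -0.15 ± 0.12, Cdx2 at 0.31 ± 0.19, Lin28a at 0.20 ± 0.10 and Pou5f1, at 1.15 to 5.89 CPM with the highest level in KO 1-3, at 0.07 ± 0.55. Cdx2 was at 0.066 without WT 1-2, 0.59 without WT 2-1 and 0.13 without KO 1-3, and Lin28a at 0.054 without WT 1-2 and 0.36 without WT 2-1. T changed sign without WT 2-1 (0.074), and Pou5f1 without WT 1-2 (-0.27) or KO 1-3 (-0.82).

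Markers of differentiating neurons had a median of -0.43 over 17 tested genes in KO against WT (camera adjusted p = 0.00113, adjusted p = 0.134 with an estimated correlation), with 3 lower when adjusted over the list alone and Ebf2 at -1.42 ± 0.28. Per library the list lay at 0.09 in KO 1-3, -0.18 in KO 2-2 and -0.25 in KO 2-3, and between -0.09 and 0.04 in the other libraries. The KO minus WT median was -0.23 without WT 1-2, -0.69 without WT 2-1 and -0.22 without KO 2-2, and without KO 2-3 the list was not called (median -0.34, camera adjusted p = 0.0504). Surface ectoderm, with 2 genes higher when adjusted over the list alone, had a median of 0.19 (camera adjusted p = 0.00172, adjusted p = 0.558 with an estimated correlation) and hindgut endoderm, with 0 by edgeR over the list alone, of 0.18 (camera adjusted p = 0.0233, adjusted p = 0.715 with an estimated correlation). In KO against Het, Grhl3 was at 0.66 ± 0.15 and Krt18 at 0.35 ± 0.08, and somite genes had a median of -0.16 (camera adjusted p = 0.00552, adjusted p = 0.536 with an estimated correlation), with Pax9 at -0.98 ± 0.25. KO 1-3 stood apart in these lists, at 0.44 for surface ectoderm, 0.53 for hindgut endoderm and -0.46 for somite genes. Without KO 1-3 the hindgut median in KO against WT was -0.059 (camera adjusted p = 0.908), without WT 1-2 it was 0.076 (camera adjusted p = 0.638), without WT 2-1 0.35 and without KO 2-2 0.30. The surface ectoderm median without KO 1-3 was 0.058 (camera adjusted p = 0.0277, adjusted p = 0.611 with an estimated correlation). The somite median in KO against Het was 0.014 without KO 1-3 (camera adjusted p = 0.843) and -0.26 without KO 2-2.

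Hypoxia and glycolysis genes had the highest median among the called lists in KO against WT, 0.54 over 20 tested genes (camera adjusted p = 2.89e-10, adjusted p = 0.517 with an estimated correlation), although 0 of them were called by edgeR over all genes or over the list alone. Slc2a1 was at 0.57 ± 0.19 and Ldha at 0.41 ± 0.14, and without KO 1-3 at 0.27 and 0.24. In KO against Het the median was 0.57 (camera adjusted p = 9.43e-12, adjusted p = 0.504 with an estimated correlation), with 0 genes called by edgeR over all genes and 15 higher when adjusted over the list alone. KO 1-3 stood apart from the other libraries, at 53.1 on the first principal component (27.8% of the variance) against -13.1 to -0.95. In KO 1-3 all 20 genes lay more than 0.5 above the mean of the WT and Het libraries, with a median of 1.03, against 0.19 in KO 2-2 and 0.18 in KO 2-3 and 0 of 20 genes in every other library. Mitochondrially encoded genes took 0.634% of the counts in KO 1-3 and 1.10% to 1.30% in the other libraries, and the mitochondrial list had a median of -0.29 (camera adjusted p = 0.00693, adjusted p = 0.681 with an estimated correlation). Without KO 1-3 the hypoxia median in KO against WT was 0.18 (camera adjusted p = 6.50e-04, adjusted p = 0.343 with an estimated correlation), that in KO against Het was 0.22 (camera adjusted p = 2.10e-07, adjusted p = 0.230 with an estimated correlation), and the mitochondrial median -0.02 (camera adjusted p = 0.459), and without WT 2-1 the mitochondrial list was not called either (camera adjusted p = 0.103). The tail Hox median without KO 1-3 was -1.43. Small-subunit ribosomal protein genes had a median of 0.15 (camera adjusted p = 0.00113, adjusted p = 0.592 with an estimated correlation) and were not called without WT 1-2 (camera adjusted p = 0.120). That list lay at 0.22 in KO 1-3, 0.034 in KO 2-2 and 0.073 in KO 2-3, and its median without KO 1-3 was 0.084 (camera adjusted p = 0.0244, adjusted p = 0.611 with an estimated correlation). Values of Rps2, in that list, and of Eno1, in the hypoxia list, are uncertain because their reads can be shared with near-identical copies.

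**Figure D4:**
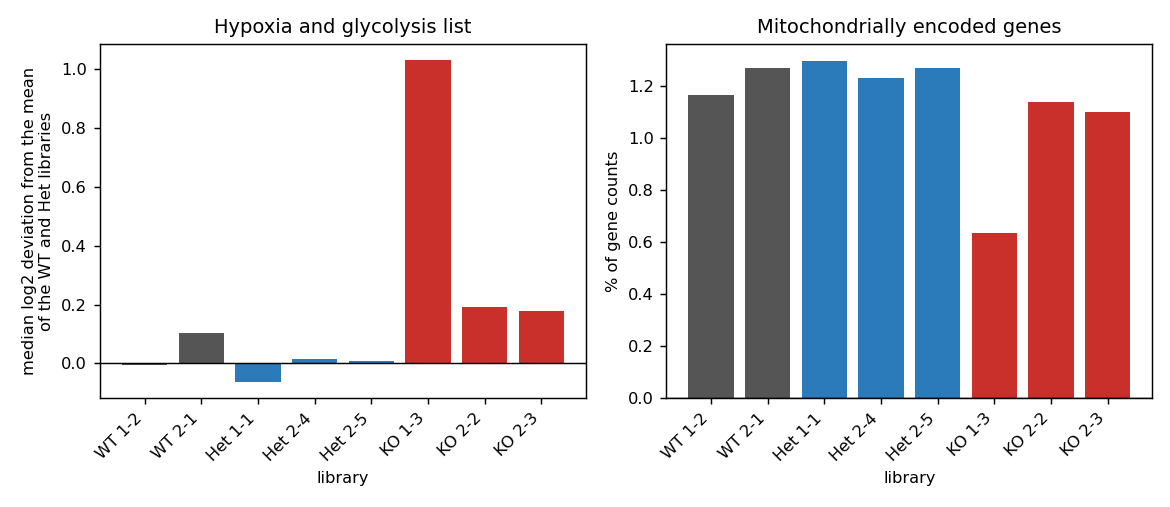
Left, median log2 deviation of the hypoxia and glycolysis genes from the mean of the WT and Het libraries, per library. Right, percent of gene counts in mitochondrially encoded genes, per library. KO 1-3 is at 1.03 on the left and 0.634% on the right.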

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

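The column-set block, limma on log2(FPKM + 1), the Y-linked covariate for the list tests and the permutation within column sets were chosen after seeing the data; the other alternatives were fixed before the data were examined. No paired analysis was possible because the data columns carry no sample number from the labels, so the planned block by replicate number was not run. Of 85 alternative counts 33 lay within 1.5 times the reported one. These include fits of Het against WT where 0 genes stood beside a reported 0, so the share overstates the stability of the KO counts. The 6 genes of KO against WT became 205 with no filter on low counts (100 higher, 105 lower), 91 with DESeq2 (25 higher, 66 lower), 20 with the Y-linked level as a covariate, 19 with the column-set block, 3 each with limma on log2(FPKM + 0.1), on log2(FPKM + 1), on values scaled by the median of ratios and on quantile-normalized values, 2 among genes of at least 5 FPKM, and 1 each with limma without trend and with only the compared libraries. Leaving out 1 library gave 1 to 28. The 31 genes of KO against Het became 437 with no filter (256 higher, 181 lower), 159 with DESeq2, 47 with the block, 18 with library weights, 10 with only the compared libraries, 7 at 5 FPKM, 4 with each of the same 4 limma settings and 1 without trend, with 2 to 49 leaving out 1 library. The 0 genes of Het against WT (edgeR, 292 at an unadjusted p below 0.05) became 11 with no filter, 2 with DESeq2 and 1 with library weights, with 0 to 1 leaving out 1 library. The 54 genes that differ between KO and the mean of WT and Het became 514 with no filter (307 higher, 207 lower), 204 with DESeq2, 107 with WT and Het as 1 group, 22 with library weights and 22 at 5 FPKM, 9 with limma on log2(FPKM + 1), median of ratios and quantiles, 8 on log2(FPKM + 0.1) and 8 without trend, and 0 in a linear trend over knockout alleles by edgeR (1343 at an unadjusted p below 0.05), with 9 to 62 leaving out 1 library. DESeq2 size factors in edgeR gave 6, 36, 0 and 54.

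The Prtg value passed the threshold with no filter (-0.48) and DESeq2 (-0.48). In KO against WT, leaving out 1 library gave Smad2 -0.059 to 0.0071, above 0 without WT 1-2 and without KO 1-3 (0.0022), Tgfbr1 -0.073 to 0.033, above 0 without KO 1-3, and T -0.35 to 0.074, above 0 without WT 2-1. Tgfbr1 turned to 0.0076 with library weights. Pou5f1 turned to -0.17 on log2(FPKM + 0.1), -0.043 with the median of ratios, -0.061 with quantiles, -0.046 both without trend and on log2(FPKM + 1) and -0.28 with weights, and ran from -0.82 without KO 1-3 to 0.50 without WT 2-1, with -0.27 without WT 1-2. Prtg in KO against Het ran from -0.072 to 0.044, above 0 without Het 2-5 and without KO 2-3 (0.019). Of 765 alternative values of the genes named for KO against WT 682 kept their direction and side of the threshold, as did 287 of 510 for KO against Het, 168 of 174 for Het against WT and 246 of 452 for KO against the mean. These shares cannot be compared, since a gene short of the threshold kept its side by staying uncalled. Of the 37 genes counted for KO against WT 6 were called, with 32 values that lost a call, and of the 9 for Het against WT 0 were called.

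With an estimated correlation and with fry, 0 lists were called in each pairwise comparison, against 14, 15 and 6 with camera, and the tail Hox list kept its medians of -1.46 and -1.49 without passing. In KO against the mean of WT and Het camera called 16 lists, fry 1, the tail Hox list (adjusted p = 0.0438), and the estimated correlation 0 (adjusted p = 0.0508 with an estimated correlation for tail Hox). On log2(FPKM + 0.1) camera called 8 lists in KO against Het and 0 in Het against WT, where the median of ratios gave 0 and the block 3. Leaving out 1 library gave 13 to 23, 12 to 19 and 2 to 12 lists. Hindgut endoderm in KO against WT ran from -0.059 without KO 1-3 to 0.35. In Het against WT the progenitor list ran from -0.18 to 0.094, above 0 without WT 2-1, and primitive erythroid genes from -0.63 to 0.38, above 0 without WT 1-2. The Hox index difference kept its sign in all settings, at -1.17 to -1.52 leaving out 1 library and -1.38 permuted within column sets, where fewer splits raise the smallest exact p. Its Het minus WT value ran from -0.23 without WT 2-1 to 0.37, with -0.051 without Het 1-1. Apart from the limit that fewer splits set on the exact p, the cause of these differences between settings was not tested. Leaving out a library or genes changes both their number and which of them enter the fit. Depth limits the precision of the Hoxd12 fold change, which rests on 0, 2 and 6 reads in the KO libraries.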

Other observations

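The tests of embryo sex, of the copies, of the column sets, of strain variants and of KO 1-3 were chosen after the results were seen. Camera called some gene groups not described above. In KO against Het (n = 3 each), Hox groups 1 to 4 had a median of 0.17 over 12 tested genes, with 3 higher when adjusted over the list alone (camera adjusted p = 0.00214, adjusted p = 0.504 with an estimated correlation). KO 1-3 lay at 0.28 and KO 2-2 at 0.096, and KO 2-3, at 0.077, lay within the WT and Het range of -0.12 to 0.090. Neuromesodermal progenitor and tailbud genes had a median of 0.10 over 27 genes, with 7 higher and 1 lower over the list alone (camera adjusted p = 0.0353, adjusted p = 0.536 with an estimated correlation), a call lost without Het 1-1, Het 2-4 or KO 2-3 (highest adjusted p = 0.260), with a median of 0.23 without Het 2-5. The KO libraries, at 0.12, 0.11 and 0.091, all lay within the WT and Het range of -0.098 to 0.18. WT 2-1 set the upper end of that range, and the KO libraries lay above every Het library (-0.098, -0.021 and 0.068). Primitive erythroid genes had a median of 0.39 (camera adjusted p = 0.00126, adjusted p = 0.545 with an estimated correlation), but the KO libraries lay at 0.05, 0.65 and 0.04 and the others between -0.40 and 0.54, and the list was not called without KO 2-2 (0.14, camera adjusted p = 0.307) or Het 2-5 (0.22, camera adjusted p = 0.0823).

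In KO against WT, a list of Prtg and related receptors and ligands, with Prtg itself (-0.47) among its 14 genes, had a median of -0.18, with 2 lower over the list alone (camera adjusted p = 0.00258, adjusted p = 0.171 with an estimated correlation), not called without WT 1-2 (-0.042, adjusted p = 0.0684) and at -0.29 without WT 2-1. The KO libraries, at -0.19, -0.060 and -0.12, lay below the WT libraries at 0.14 and -0.055. KO 2-2, at -0.060, lay close to WT 2-1 and above Het 2-5 at -0.065. Genes near Prtg on chromosome 9, among them Mns1 (-0.66 ± 0.10), had a median of -0.10 over 13 genes, with 1 higher and 4 lower over the list alone (camera adjusted p = 1.90e-04, adjusted p = 0.137 with an estimated correlation). The KO libraries, at -0.074, -0.028 and -0.105, lay below the WT libraries at 0.059 and 0.045. KO 2-2, at -0.028, lay within the Het range of -0.045 to 0.0088. p53 targets had a median of 0.15 (camera adjusted p = 0.00157, adjusted p = 0.229 with an estimated correlation), not called without WT 1-2 (0.089, adjusted p = 0.0974). Immediate early and heat shock genes had a median of -0.07 but a mean of 0.11 and were called lower by camera (adjusted p = 0.0396, adjusted p = 0.330 with an estimated correlation), a call lost without WT 2-1 (median 0.0014, adjusted p = 0.284), KO 2-2 or KO 2-3 (-0.12). The median was -0.12 without WT 1-2 and -0.0085 without KO 1-3.

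The count of genes that differed between KO and the 5 other libraries taken as 1 group was 107. Of the 56 splits of the 8 libraries into 3 and 5, 1 gave as many, the real one, and the highest other gave 10. That share, 0.0179, is the smallest that 56 splits allow, so the test makes chance less likely but cannot exclude it. The splits were not made within column sets. Every other split mixed KO libraries with the others in a group, which can widen the spread within groups and lower the count. The split by column set gave 4. For KO against Het, 1 of 10 splits, the real one, gave 31 genes and the highest other 8, and 10 splits are too few for a share under 0.05.

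Tail Hox genes were lower in all 3 KO libraries, at -1.76 in KO 1-3, -1.30 in KO 2-2 and -1.07 in KO 2-3, against -0.29 to 0.25 in the others. Embryo sex as the whole cause was argued against, since with the Y-linked level as a covariate the median stayed at -1.53. A general loss of lateral plate and limb bud tissue as large as the tail Hox median of -1.48 was argued against by a list median of -0.018 (SD over members 0.401), or -0.13 over the 14 members above 20 CPM, of which 5 lay at or above 0. Camera did not call the list with all libraries (adjusted p = 0.0779) but called it lower at -0.070 both without KO 1-3 (adjusted p = 0.0438, adjusted p = 0.478 with an estimated correlation) and without Het 2-5 (adjusted p = 0.0226, not called with an estimated correlation either). In KO against Het camera called the list lower at -0.12 without KO 1-3 and at -0.16 without Het 2-5 (adjusted p = 0.504 and 0.306 with an estimated correlation). A smaller loss stays open, as does a loss of posterior tissue alone, with Tbx4 at -0.93, Isl1 at -0.68 and Pitx1 at -0.47. Neuromesodermal progenitor and tailbud genes, at 0.12, 0.11 and 0.091 in the KO libraries, lay within the WT and Het range of -0.098 to 0.18. An earlier stage of the KO embryos may contribute: differentiating neuron genes had a median of -0.23 (camera p = 0.00113, adjusted p = 0.227 with an estimated correlation). However, KO 1-3, the library with the lowest tail Hox level, lay at 0.09. In KO against Het the median was -0.12, and camera did not call the list without Het 2-4 (adjusted p = 0.0538) or KO 2-3 (adjusted p = 0.241). Trunk-stage regulators, at 0.043, 0.049 and -0.032 in the KO libraries, lay within the WT and Het range of -0.088 to 0.14. An effect of Prtg loss itself stays open too, as a hypothesis.

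The 50 autosomal genes with the most spread between libraries of 1 genotype, KO 1-3 left out, included Atp6v0c, its copy Atp6v0c-ps2 and the Eno1 copies Eno1b and Gm4735, but neither Eno1 nor Rps2. For Atp6v0c, Eno1 and Rps2, shared reads are a candidate explanation, since the highest sum of gene and copies was at most 1.15 times the lowest, while the gene alone differed at least 1.57-fold, with KO 1-3 left out of both. A single processing difference between the column sets was argued against for Rps2, whose share in its copy ranged over 44.6 percentage points within the second set, at 5.71% in WT 2-1 and 5.15% in KO 2-2 and 48.6% to 49.8% in Het 2-4, Het 2-5 and KO 2-3. For Eno1 that explanation stays open, with a gap of 28.8 points between the sets and ranges of at most 1.14 within them. Atp6v0c had 41.8% to 45.1% of its counts in its copy in Het 2-4, Het 2-5 and KO 2-3 and at most 0.921% elsewhere. Gm9825 was at 79.3 to 86.3 CPM in those libraries and at most 2.40 elsewhere. Shared reads alone leave open why the split differed between libraries, so they and a variant carried by some embryos cannot be told apart here. Strain variants carried by some embryos could also account for part of the spread: 4 of the 50 genes, Rps18, AC165951.1, Glo1 and H2-Ab1, lay in 1 window of 5 Mb on chromosome 17 (30584936 to 35584936), against a 95th percentile of 3 in 10000 random draws (permutation p = 0.0481). The spread of these 4 genes lay between KO 2-2 and KO 2-3, which fell on opposite sides of the WT and Het range. Rps18, for example, was at 749 CPM in KO 2-2 and 17.1 CPM in KO 2-3, against 323 to 383 CPM in the WT and Het libraries.

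Hypoxia and glycolysis genes were high in KO 1-3, at a list median of 1.03, with Pfkp at 219 CPM against 15.5 to 21.1 in the others, Ddit4 at 427 against 30.4 to 77.2 and Mt1 at 81.5 against 5.15 to 10.3. Loss of Prtg as the whole cause was argued against, since the higher of the other KO libraries lay at 0.190. KO 2-2 (0.190) and KO 2-3 (0.178) still lay above the WT and Het range of -0.063 to 0.10, so a smaller rise with the loss of Prtg stays open. A few genes taking most of the counts was argued against by a share of 5.36% in the 10 most abundant genes, with 5.12% as the highest elsewhere. A difference in the handling or the state of that embryo may remain, and it was not tested.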
